A study of Homo sapiens with 15 samples.

How the data were processed

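The samples were 15 bulk RNA-seq libraries of H9 human embryonic stem cells, 3 per day of differentiation from day 0 to day 4. Per the labels' protocols, RNA was purified with a column kit, polyA RNA was selected and strand-specific libraries were made. Per the submitters' processing notes, TopHat2 2.0.14 and the human build hg19 were used. The counting program, its gene annotation and whether it used strand are not given in the sources used here, so levels of antisense and overlapping genes are uncertain. The authors deposited a table of gene counts, whole numbers per gene symbol and library with no normalization. Each library's column was matched to its sample by the title in the labels, which gives the replicate number and the day.

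The table had 23398 entries. Of 52 entries that repeated a symbol, 44 had identical values and were dropped and 8 were summed, leaving 23346 symbols, 2605 of them with no count in any library. No value was odd: all counts were even, as when both mates of a read pair are counted. Total counts were 95094932, 105500378 and 98853486 for replicates 1, 2 and 4 of day 0, 72266892, 69264028 and 100685830 for day 1, 115442078, 80568014 and 70785986 for day 2, 145857940, 65534538 and 86622154 for day 3 and 97914714, 98048836 and 54723184 for day 4. A count of 3 corresponded to 0.0206 to 0.0548 CPM. Libraries of a day differed by far more than counting noise: chi-square per degree of freedom over genes ran from 42.9 to 624 for the pairs, so no library was taken for a copy of another.

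The main test was edgeR's quasi-likelihood F-test (edgeR 4.0.16, limma 3.58.1, R 4.3.3) on the counts as deposited, with TMM scaling, genes filtered with filterByExpr by day (17401 kept), a mean per day and all 15 libraries in a single fit, so that the days shared an estimate of spread. The biological coefficient of variation was 45.5%. Benjamini-Hochberg adjusted p under 0.05 was called. The consecutive days and day 4 against day 0 were compared, the days were tested jointly, and genes above both ends on day 1 were counted. CPM values, counts scaled to a common library size, use the TMM-scaled library sizes. DESeq2 1.42.0 was an alternative. Tables were prepared with Python 3.11.15 and pandas 2.3.3.

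Tested on simulated data drawn from these libraries with 100 genes changed 2-fold and 100 changed 4-fold among 17401, edgeR recovered 0% of the 2-fold and 52% of the 4-fold changes for day 1 vs day 0, with 4 unchanged genes called, and 1% and 48% for day 4 vs day 3, with 0 unchanged genes called. DESeq2 recovered 13% and 81% for day 1 vs day 0, with 39 unchanged genes called, and 16% and 87% for day 4 vs day 3, with 26. Changes of about 2-fold were thus mostly not detected by edgeR in this simulation. It changed fewer genes than were called on day 1 or day 4 vs day 0 in the data, which makes the adjusted threshold stricter. In the data, day 4 vs day 0 had calls down to an absolute log2 fold change of 0.594. Genes were drawn independently, without trends shared within a library, so false calls may be more frequent in the data.

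A set of 28 gene lists was written from general knowledge: pluripotency, naive pluripotency, primitive streak, definitive endoderm, later endoderm and gut tube, extraembryonic endoderm, mesoderm, blood and endothelium, neural and surface ectoderm, trophoblast and amnion, metallothioneins, zinc and copper handling, Wnt, activin and Nodal, BMP, p53 and hypoxia targets, FGF and ERK feedback, epithelial, mesenchymal transition, basement membrane, glycolysis, oxidative phosphorylation, cholesterol synthesis, S phase, mitosis, ATF4 stress response and heat shock. Some genes are in more than a single list. Each list was tested in each comparison with camera at a preset correlation of 0.01 (main), camera with an estimated correlation and fry, adjusted over the 28 lists of a comparison. The genes named were fixed by a rule with several parts: in each comparison the 6 largest increases and 6 largest decreases among called genes with a mean of at least 5 CPM and no overlap between the libraries of both days; a fixed set of pluripotency, streak and endoderm genes, AXIN2 and the metallothioneins; and per list the up to 4 called members with the largest change or, with none called, the 2 of highest level. Groups, comparisons, tests, lists, this rule and the first set of alternatives were chosen before the data were examined. A few genes that the rule names are not reported here.

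Those alternatives were DESeq2's size factors in edgeR, library totals alone, no filter, a filter of CPM over 1 in 3 libraries, DESeq2, the replicate number as a block, a fit of only the days compared, a test against a 1.5-fold change, and each library left out in turn. Added after the data were seen were counts halved, transcript length and GC trends removed per library by offsets, the same with the block, and a fit without replicate 1 of days 3 and 4. Lengths and GC contents came from a GRCh38 annotation, not the authors' build, and no coordinates were taken from it; 20194 symbols matched directly and 1459 through an older symbol, and 16461 of 17401 tested genes (94.6%) had a value. Whether the numbers pair the libraries was checked by correlating deviations from the means of a day, over genes. Same-numbered libraries correlated above 0.1 in every pair for day 3 vs day 2 (0.272, 0.385 and 0.619 for replicates 1, 2 and 4) and for day 4 vs day 3 (0.625, 0.221 and 0.524), and the numbers were taken to pair the libraries there, a pairing that comes from the data and not from the labels. Some libraries of different number also passed 0.1, such as day 2 replicate 1 with day 3 replicate 2 (0.243). In both comparisons, however, 6 of 6 libraries correlated best with their own number. Whether a technical trend shared by a number made these correlations was not tested.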

Results

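H9 cells, an established human embryonic stem cell line, were sampled while they were differentiated to definitive endoderm, the germ layer that gives rise to gut, liver and pancreas. Undifferentiated cells in E8 medium were the day 0 group. Differentiation ran in Advanced RPMI medium with activin A, a ligand that signals as Nodal does, and during the first day also with CHIR99021, a GSK3 inhibitor that activates Wnt signalling; activin A was then given alone. RNA was taken daily from day 0 to day 4, with 3 libraries per day numbered 1, 2 and 4, and 15 polyA-selected bulk libraries were read. The total count per library ran from 54723184 in day 4 replicate 4 to 145857940 in day 3 replicate 1. The design text calls the experiments triplicates, and no label says that the 3 libraries of a day came from separate cultures, so p-values measure the spread between these samples only, which may be technical. Day 0 also differed from the later days in culture medium, so day and medium were not separable in any comparison with day 0. Levels are CPM, counts scaled to library size, as mean ± SD of the 3 libraries of a day, and log2 fold changes are the later day minus the earlier one with an approximate standard error (SE). The SE was derived from the test, as the absolute log2 fold change divided by the square root of its F statistic.

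Across the course, 6498 of 17401 tested genes changed by the joint test of the 5 days. The streak gene MIXL1 went from 2.3 ± 0.378 CPM on day 0 to 1197 ± 34.2 on day 1 and 101 ± 84.2 on day 4, while the endoderm gene SOX17 went from 0.844 ± 0.157 on day 0 and 0.656 ± 0.369 on day 1 to 82.9 ± 14 on day 2 and 175 ± 89.6 on day 4. SOX2, a pluripotency factor, went from 201 ± 97.9 CPM on day 0 to 1.15 ± 0.538 on day 1 and 8.17 ± 5.74 on day 4. Among the changed genes, the highest mean fell on day 0 for 2296, on day 1 for 1024, on day 2 for 459, on day 3 for 1261 and on day 4 for 1458.

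**Figure D1:**
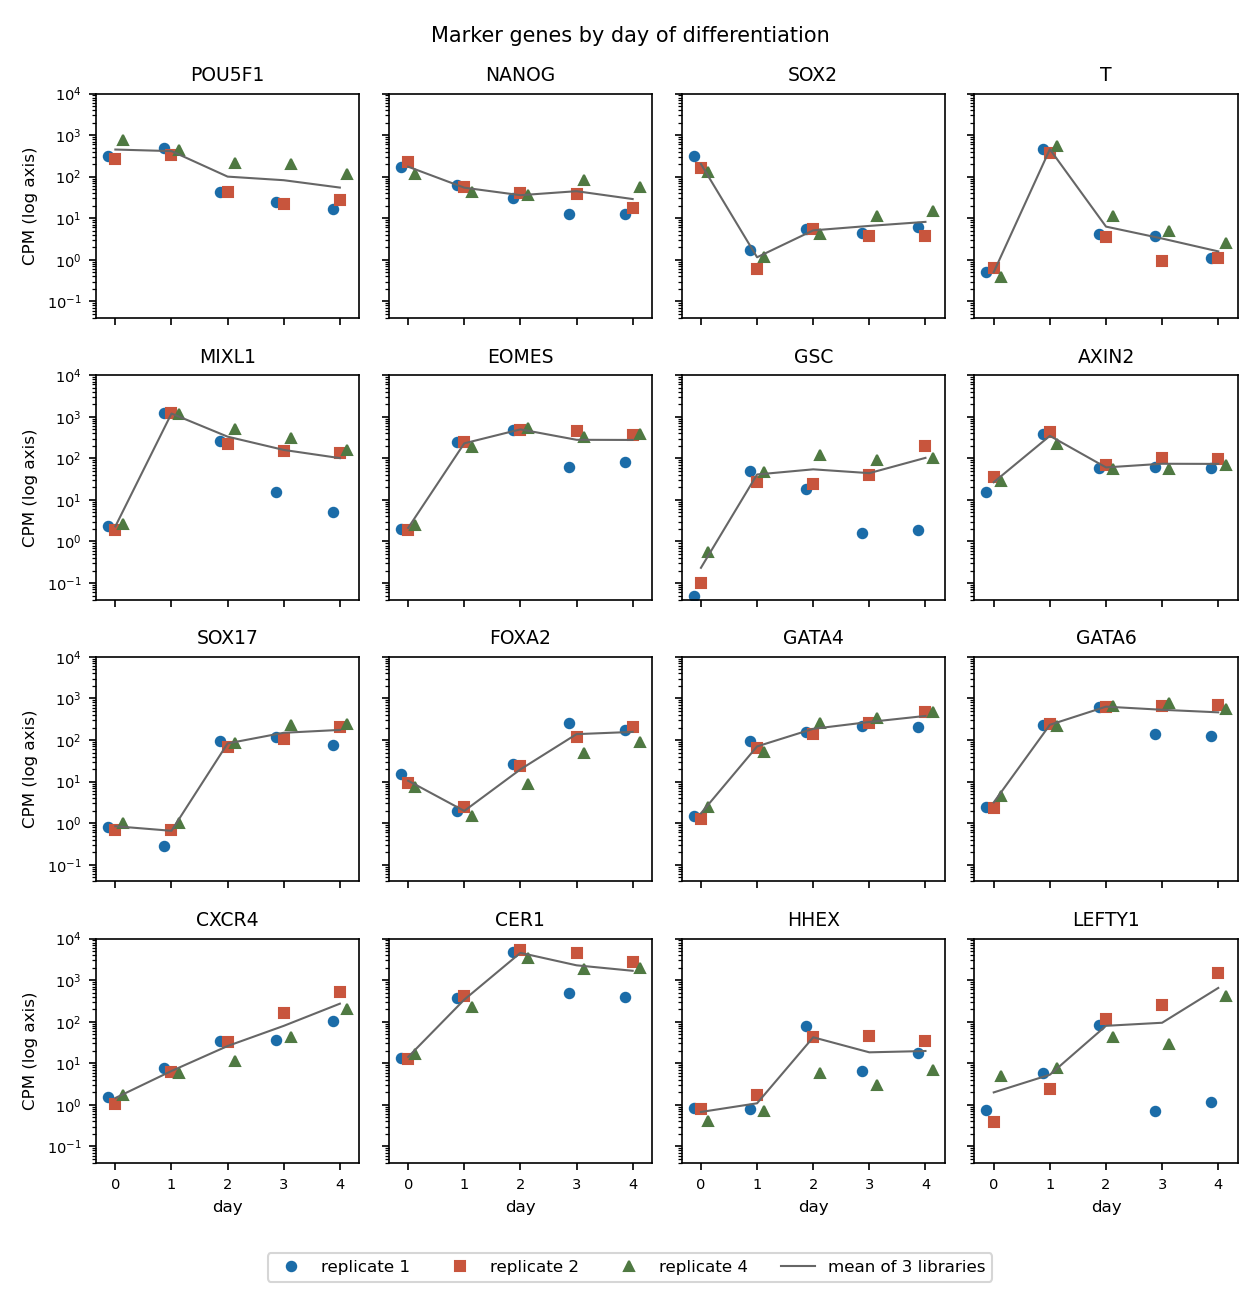
CPM (log axis, values under 0.05 drawn at 0.05) of 16 marker genes in each of the 15 libraries by day, each point a library. MIXL1 is highest on day 1 (mean 1197 CPM), and SOX17 moves from a mean of 0.656 CPM on day 1 to 82.9 on day 2.

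The first comparison asked what a day of activin A with CHIR99021 did. Genes of the primitive streak, the site where mesoderm and endoderm arise in the embryo, rose together: T (brachyury, log2 fold change 9.82, SE 0.77, adjusted p = 1.16e-06) went from 0.504 ± 0.128 to 456 ± 89.4 CPM and the homeobox gene MIXL1 from 2.3 ± 0.378 to 1197 ± 34.2 CPM (log2 fold change 9.02, SE 1.24). Wnt feedback genes rose with them, among them DKK1 from 4.54 ± 2.08 to 2987 ± 193 CPM and AXIN2 from 26.6 ± 10.5 to 348 ± 111 CPM. SOX2 fell by 7.45 on the log2 scale (SE 0.70, adjusted p = 5.63e-06), whereas POU5F1, the OCT4 gene, stood at 449 ± 276 CPM on day 0 and 412 ± 80 on day 1 (log2 fold change -0.12, SE 0.86, adjusted p = 0.953) and did not pass the test. By edgeR's quasi-likelihood test, 956 genes were higher and 850 lower on day 1 than on day 0. The higher count was 624 without day 0 replicate 1 and 1484 without day 0 replicate 4, and the lower count was 541, 380, 401 and 452 without day 0 replicate 1 and without day 1 replicates 1, 2 and 4 in turn.

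Of 19 measured primitive streak genes, 17 were higher, 1 lower and 1 not called (17 higher and 2 lower adjusted over the list alone). Primitive streak genes had a median log2 fold change of 7.42 (camera adjusted p = 3.5e-29). Members that rose included the homeobox genes EVX1 (log2 fold change 9.68, SE 1.44) and CDX1 (9.19, SE 0.79). In the Wnt target list, 18 of 21 measured genes were higher, 0 lower and 3 not called (20 higher and 0 lower adjusted over the list alone). The median of Wnt target genes was 4.41 on the log2 scale (camera adjusted p = 7.28e-45). DKK4, a secreted Wnt antagonist, rose from 1.31 ± 0.111 to 1330 ± 404 CPM, and CDX2 from 0.107 ± 0.0508 to 75.6 ± 22.7 CPM. Of 19 measured mesoderm genes, 10 were higher, 0 lower and 9 not called, with equal counts adjusted over the list alone. Mesoderm genes had a median log2 fold change of 3.38 (camera adjusted p = 4.55e-09; adjusted p = 0.0621 with an estimated correlation). MSGN1, a regulator of presomitic mesoderm, rose from 0.019 ± 0.033 to 24.4 ± 1.05 CPM, and MESP1 (7.96, SE 1.48), FOXF1 (7.06, SE 0.74) and FOXC1 (6.54, SE 1.00) also rose on the log2 scale. In the BMP target list, 13 of 18 measured genes were higher, 0 lower and 5 not called (15 higher and 0 lower adjusted over the list alone). The median of BMP target genes was 3.33 on the log2 scale (camera adjusted p = 5.32e-16; adjusted p = 0.0509 with an estimated correlation). MSX1 (8.60, SE 1.33), MSX2 (5.53, SE 0.64) and BMP2 itself (4.95, SE 0.41) rose. Of 17 measured activin and Nodal target genes, 9 were higher, 1 lower and 7 not called (10 higher and 3 lower adjusted over the list alone). Activin and Nodal target genes had a median log2 fold change of 1.80 (camera adjusted p = 1.77e-07). NODAL rose from 2.9 ± 0.861 to 412 ± 114 CPM and EOMES, a T-box factor of streak and endoderm, from 2.12 ± 0.306 to 229.7 ± 37.6 CPM. Genes named for the size of their increase also included the receptor gene TNFRSF9 (9.99, SE 1.46).

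Of 22 measured pluripotency genes, 1 was higher, 8 lower and 13 not called (1 higher and 14 lower adjusted over the list alone). Pluripotency genes had a median log2 fold change of -1.35 (camera adjusted p = 1.22e-09). FOXD3 (-8.01, SE 0.68), SOX2 and PRDM14 (-3.87, SE 0.66) were among the members that fell, and NODAL was the member that rose. NANOG stood at 174 ± 55.7 and 54.3 ± 10.8 CPM (adjusted p = 0.0868). In the naive pluripotency list, 2 of 11 measured genes were higher, 3 lower and 6 not called, with equal counts adjusted over the list alone. The median of naive pluripotency genes was 0.40 on the log2 scale (camera adjusted p = 0.984), although their mean was -0.52. TBX3 (5.94, SE 0.88) and KLF5 (3.83, SE 0.34) rose and DPPA3 (-3.80, SE 0.82) fell. Of 21 measured mesenchymal transition genes, 12 were higher, 1 lower and 8 not called (14 higher and 2 lower adjusted over the list alone). Mesenchymal transition genes had a median log2 fold change of 2.12 (camera adjusted p = 4.05e-15). The repressor gene ZEB2 rose from 1.56 ± 0.833 to 34 ± 9.1 CPM, the cadherin gene CDH11 from 21.6 ± 4.11 to 309 ± 40.6 CPM and the collagen gene COL1A2 from 55.2 ± 9.81 to 683 ± 79.1 CPM. In the epithelial list, 0 of 23 measured genes were higher, 3 lower and 20 not called (1 higher and 5 lower adjusted over the list alone). The median of epithelial genes was -0.77 on the log2 scale (camera adjusted p = 0.00911; adjusted p = 0.503 with an estimated correlation). CLDN3, a tight junction gene, fell from 3.93 ± 2.22 to 0.20 ± 0.131 CPM. Of 20 measured neural and surface ectoderm genes, 0 were higher, 5 lower and 15 not called (0 higher and 7 lower adjusted over the list alone). Neural and surface ectoderm genes had a median log2 fold change of -0.65 (camera adjusted p = 0.00281; adjusted p = 0.0621 with an estimated correlation). SOX21 (-5.39, SE 1.08), HESX1 (-4.74, SE 0.71) and POU3F1 (-4.72, SE 0.57) were lower on the log2 scale. Genes named for the size of their decrease included FOXJ1 (-6.89, SE 1.13), a ciliary transcription factor, and SORBS2 (-6.61, SE 0.70).

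Of 24 measured definitive endoderm genes, 12 were higher, 3 lower and 9 not called, with equal counts adjusted over the list alone. Definitive endoderm genes had a median log2 fold change of 1.54 (camera adjusted p = 5.95e-07; adjusted p = 0.14 with an estimated correlation). GATA6 rose from 3.17 ± 1.27 to 232 ± 14.9 CPM, GATA4 from 1.72 ± 0.642 to 70.2 ± 22.9 CPM, CER1, a secreted Nodal and BMP antagonist, from 14.2 ± 1.93 to 339 ± 98.8 CPM and FGF17 from 2.93 ± 2.45 to 144 ± 28.3 CPM. Other endoderm genes did not yet pass: HHEX was at 0.675 ± 0.242 CPM on day 0 and 1.09 ± 0.584 on day 1 (adjusted p = 0.704) and LEFTY1 at 2.0 ± 2.48 and 5.32 ± 2.72 (adjusted p = 0.634). FOXA2, a forkhead factor of endoderm, was lower on day 1 (10.5 ± 3.86 against 1.97 ± 0.499 CPM, adjusted p = 0.0102), a call lost with adjusted p = 0.0503 without day 0 replicate 1 and 0.0565 without day 1 replicate 4. In the extraembryonic endoderm list, 4 of 14 measured genes were higher, 1 lower and 9 not called (5 higher and 1 lower adjusted over the list alone). The median of extraembryonic endoderm genes was 0.61 on the log2 scale (camera adjusted p = 0.00509; adjusted p = 0.0659 with an estimated correlation). RSPO3 (7.83, SE 1.12) and PDGFRA (3.38, SE 0.60) rose. Of 15 measured later endoderm and gut tube genes, 2 were higher, 1 lower and 12 not called (2 higher and 3 lower adjusted over the list alone). Later endoderm and gut tube genes had a median log2 fold change of 0.45 (camera adjusted p = 0.665). In the blood and endothelium list, 4 of 15 measured genes were higher, 2 lower and 9 not called, with equal counts adjusted over the list alone. The median of blood and endothelium genes was 0.46 on the log2 scale (camera adjusted p = 0.0534; adjusted p = 0.365 with an estimated correlation). LMO2 (5.03, SE 0.41) and SOX18 (5.28, SE 0.82) rose, and the list passed with adjusted p = 0.0493 without day 0 replicate 4, 0.0485 without day 1 replicate 2 and 0.0251 without day 1 replicate 4. Of 13 measured trophoblast and amnion genes, 5 were higher, 1 lower and 7 not called (6 higher and 2 lower adjusted over the list alone). Trophoblast and amnion genes had a median log2 fold change of 0.74 (camera adjusted p = 0.0607; adjusted p = 0.438 with an estimated correlation). WNT6 rose (8.12, SE 1.55), and this list passed with adjusted p = 0.0166 without day 1 replicate 4.

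Of 25 measured cholesterol synthesis genes, 0 were higher, 5 lower and 20 not called (0 higher and 7 lower adjusted over the list alone). Cholesterol synthesis genes had a median log2 fold change of -0.84 (camera adjusted p = 3.32e-04; adjusted p = 0.162 with an estimated correlation). FDFT1 fell from 1057 ± 206 to 375 ± 40.1 CPM and ACAT2 from 364 ± 108 to 131 ± 10.1 CPM. In the glycolysis list, 2 of 21 measured genes were higher, 0 lower and 19 not called, with equal counts adjusted over the list alone. The median of glycolysis genes was 0.10 on the log2 scale (camera adjusted p = 0.687). The glucose transporter gene SLC2A3 rose from 933 ± 135 to 3047 ± 678 CPM. Of 30 measured S phase genes, 0 were higher, 0 lower and 30 not called, with equal counts adjusted over the list alone. S phase genes had a median log2 fold change of 0.06 (camera adjusted p = 0.685). In the mitosis list, 1 of 30 measured genes was higher, 1 lower and 28 not called, with equal counts adjusted over the list alone. The median of mitosis genes was -0.27 on the log2 scale (camera adjusted p = 0.178; adjusted p = 0.671 with an estimated correlation). CENPE rose (1.62, SE 0.32), BUB3 fell (-1.21, SE 0.24), and the list passed with adjusted p = 0.0434 without day 0 replicate 4. Of 17 measured FGF and ERK feedback genes, 3 were higher, 4 lower and 10 not called (5 higher and 5 lower adjusted over the list alone). FGF and ERK feedback genes had a median log2 fold change of -0.40 (camera adjusted p = 0.732), although their mean was 0.12. SPSB1 rose (2.12, SE 0.42). In the p53 target list, 1 of 24 measured genes was higher, 1 lower and 22 not called, with equal counts adjusted over the list alone. The median of p53 target genes was 0.41 on the log2 scale (camera adjusted p = 0.228). BTG2 rose (2.21, SE 0.35). Of 22 measured ATF4 stress response genes, 1 was higher, 0 lower and 21 not called, with equal counts adjusted over the list alone. ATF4 stress response genes had a median log2 fold change of 0.69 (camera adjusted p = 0.0118; adjusted p = 0.535 with an estimated correlation). In the heat shock list, 0 of 16 measured genes were higher, 0 lower and 16 not called, with equal counts adjusted over the list alone. The median of heat shock genes was 0.01 on the log2 scale (camera adjusted p = 0.732), although their mean was -0.14. HSPA8 was at 4943 ± 952 and 3960 ± 891 CPM. Of 17 measured hypoxia target genes, 0 were higher, 2 lower and 15 not called, with equal counts adjusted over the list alone. Hypoxia target genes had a median log2 fold change of -0.03 (camera adjusted p = 0.665). ADM fell from 102 ± 37.8 to 5.76 ± 2.27 CPM. In the zinc and copper handling list, 2 of 30 measured genes were higher, 1 lower and 27 not called (2 higher and 2 lower adjusted over the list alone). The median of zinc and copper handling genes was -0.05 on the log2 scale (camera adjusted p = 0.685). SLC39A8, a zinc importer gene, rose from 30.8 ± 9.56 to 197 ± 37.8 CPM. Of 20 measured basement membrane genes, 1 was higher, 0 lower and 19 not called (4 higher and 0 lower adjusted over the list alone). Basement membrane genes had a median log2 fold change of 0.52 (camera adjusted p = 0.0213; adjusted p = 0.503 with an estimated correlation). LAMB1 rose (1.44, SE 0.34). The call of the basement membrane list was lost with adjusted p = 0.177 without day 0 replicate 1 and with transcript length and GC trends removed (adjusted p = 0.238).  In the oxidative phosphorylation list, 0 of 56 measured genes were higher, 2 lower and 54 not called (0 higher and 0 lower adjusted over the list alone). The median of oxidative phosphorylation genes was -0.41 on the log2 scale (camera adjusted p = 0.0337; adjusted p = 0.782 with an estimated correlation). The list call ended with adjusted p = 0.922 without day 0 replicate 1 and 0.0861 without day 1 replicate 2, and the median without day 0 replicate 1 was 0.03. It also ended with those trends removed (adjusted p = 0.253). Day 0 replicate 1 had the highest share of ribosomal protein RNA, 7.35% of its counts against 2.13% and 4.74% in the other day 0 libraries.

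**Figure D2:**
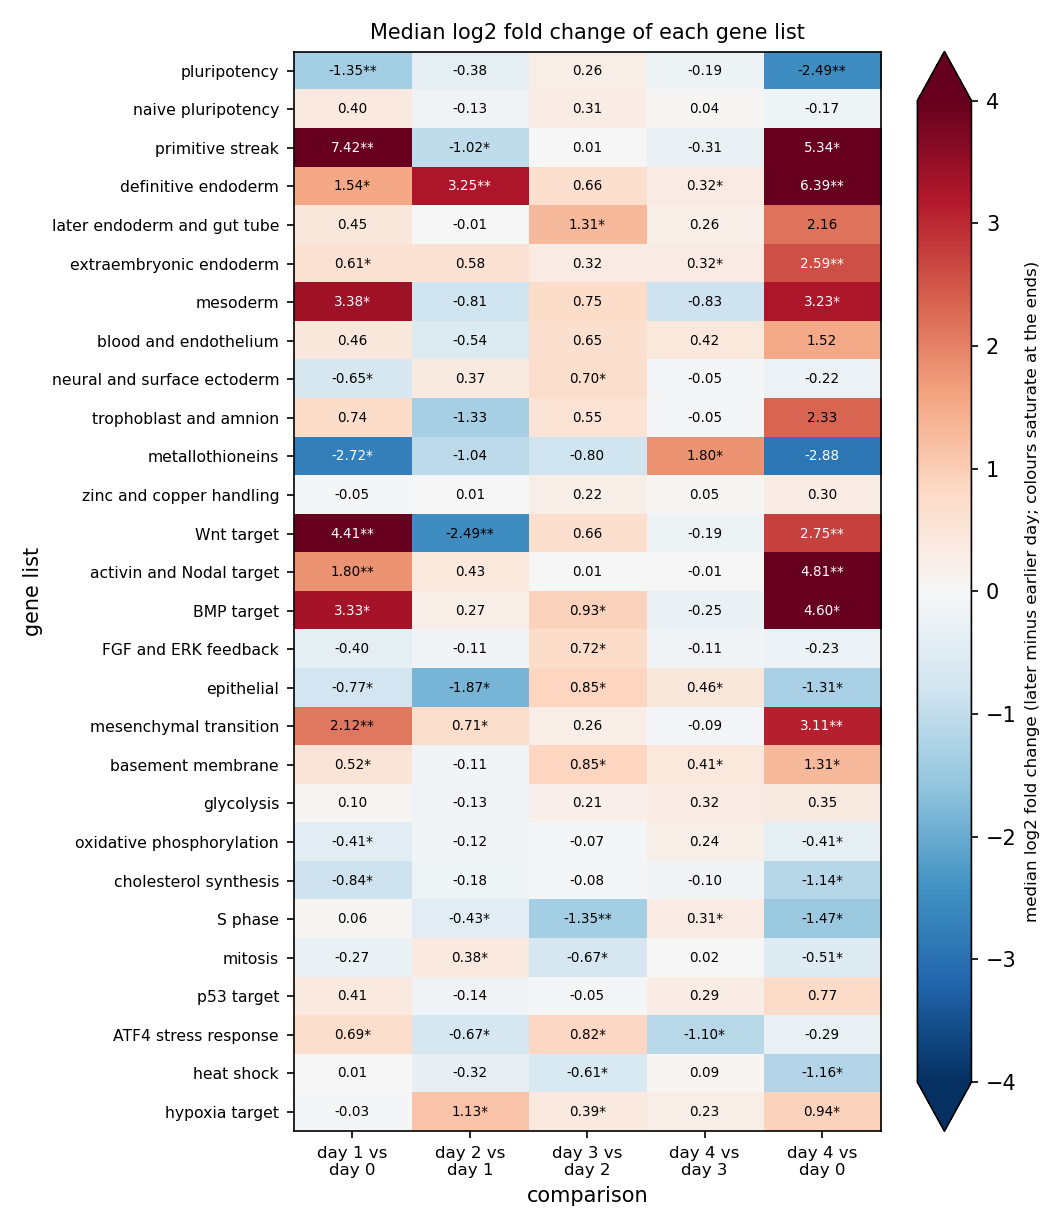
Median log2 fold change of each of the 28 gene lists (vertical) in each of the 5 comparisons (horizontal), with an asterisk where camera called the list at the preset correlation and a pair of asterisks where it was also called with an estimated correlation. The primitive streak list has the highest median of day 1 vs day 0, 7.42, and the definitive endoderm list has 3.25 in day 2 vs day 1.

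The second comparison covered the day on which CHIR99021 was withdrawn. SOX17 rose from 0.656 ± 0.369 to 82.9 ± 14 CPM (log2 fold change 6.96, SE 0.59, adjusted p = 7.35e-06), CER1 from 339 ± 98.8 to 4537 ± 985 CPM and HHEX, a homeobox gene of anterior endoderm, from 1.09 ± 0.584 to 42.2 ± 36.4 CPM. The streak gene T fell from 456 ± 89.4 to 6.28 ± 4.19 CPM (log2 fold change -6.18, SE 0.66, adjusted p = 4.78e-05), CDX1 from 91.5 ± 27 to 0.307 ± 0.115 CPM and AXIN2 from 348 ± 111 to 60.5 ± 8.07 CPM. MIXL1 stood at 1197 ± 34.2 and 332 ± 158 CPM and EOMES at 229.7 ± 37.6 and 498 ± 43.9, and neither passed (adjusted p = 0.244 and 0.269). The fit took the spread of a gene from all days, and both genes varied widely on days 3 and 4. EOMES was at 60.3 CPM in day 3 replicate 1 against 452 and 326 in replicates 2 and 4. MIXL1 was at 5.24 CPM in day 4 replicate 1 against 136 and 163. These p-values therefore do not show that either gene was unchanged. By edgeR, 857 genes were higher and 582 lower on day 2. The higher count was 384, 442 and 501 without day 1 replicates 1, 2 and 4 in turn and 490 without day 2 replicate 2; the lower count was 228, 265 and 312 without those day 1 libraries, and 239 and 183 without day 2 replicates 1 and 2.

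Of 24 measured definitive endoderm genes, 15 were higher, 1 lower and 8 not called (19 higher and 1 lower adjusted over the list alone). Definitive endoderm genes had a median log2 fold change of 3.25 (camera adjusted p = 8.24e-21). FOXA2 rose from 1.97 ± 0.499 to 19.7 ± 9.43 CPM and the receptor gene ERBB4 from 4.57 ± 2.19 to 164 ± 87.9 CPM, while DKK4, which is also a Wnt target, fell from 1330 ± 404 to 34.2 ± 21.9 CPM. In the Wnt target list, 0 of 21 measured genes were higher, 14 lower and 7 not called (1 higher and 19 lower adjusted over the list alone). The median of Wnt target genes was -2.49 on the log2 scale (camera adjusted p = 4.64e-21). DKK1 fell from 2987 ± 193 to 96.7 ± 70.3 CPM and CDX2 from 75.6 ± 22.7 to 0.567 ± 0.435 CPM. Of 19 measured primitive streak genes, 2 were higher, 7 lower and 10 not called (2 higher and 8 lower adjusted over the list alone). Primitive streak genes had a median log2 fold change of -1.02 (camera adjusted p = 7.78e-05; adjusted p = 0.202 with an estimated correlation). WNT3A (-5.56, SE 0.98) and EVX1 (-5.52, SE 1.18) fell on the log2 scale. In the epithelial list, 0 of 23 measured genes were higher, 9 lower and 14 not called (1 higher and 14 lower adjusted over the list alone). The median of epithelial genes was -1.87 on the log2 scale (camera adjusted p = 2.28e-09; adjusted p = 0.202 with an estimated correlation). OVOL1 fell (-2.85, SE 0.58); CDH1, the E-cadherin gene, was at 275 ± 13 and 31.2 ± 20.9 CPM, a decrease at adjusted p = 0.0283 that was lost with adjusted p = 0.0797 without day 1 replicate 1, 0.0803 without day 1 replicate 2, 0.0722 without day 1 replicate 4, 0.129 without day 2 replicate 1 and 0.141 without day 2 replicate 2. Of 17 measured FGF and ERK feedback genes, 1 was higher, 3 lower and 13 not called (1 higher and 4 lower adjusted over the list alone). FGF and ERK feedback genes had a median log2 fold change of -0.11 (camera adjusted p = 0.42). The immediate early genes EGR1 (-6.67, SE 0.83) and FOS (-3.12, SE 0.61) fell and the phosphatase gene DUSP4 rose (3.03, SE 0.41). In the S phase list, 0 of 30 measured genes were higher, 1 lower and 29 not called (0 higher and 0 lower adjusted over the list alone). The median of S phase genes was -0.43 on the log2 scale (camera adjusted p = 0.0032; adjusted p = 0.634 with an estimated correlation). Of 17 measured hypoxia target genes, 1 was higher, 1 lower and 15 not called (3 higher and 1 lower adjusted over the list alone). Hypoxia target genes had a median log2 fold change of 1.13 (camera adjusted p = 0.0189; adjusted p = 0.617 with an estimated correlation). MXI1 rose (2.08, SE 0.35). In the ATF4 stress response list, 1 of 22 measured genes was higher, 0 lower and 21 not called, with equal counts adjusted over the list alone. The median of ATF4 stress response genes was -0.67 on the log2 scale (camera adjusted p = 0.0032; adjusted p = 0.634 with an estimated correlation). The mitosis list (median 0.38, camera adjusted p = 0.0444) and the mesenchymal transition list (median 0.71, camera adjusted p = 0.0373) were called upward. With an estimated correlation their adjusted p was 0.634 and 0.564. In the mesoderm list, MSGN1 fell from 24.4 ± 1.05 to 0.0525 ± 0.0456 CPM and HAND1 rose from 13.5 ± 4.7 to 123 ± 81.8 CPM. Named for the size of their change were OAS1 (8.07, SE 1.16), an interferon-induced gene, RTL1 (7.72, SE 0.62) and SEMA6D (7.06, SE 0.46), which rose, and EDAR (-7.15, SE 1.10), which fell.

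Genes raised on day 1 were counted as those above both ends of the course, day 0 and day 4. The days between day 1 and day 4 were not part of this rule, so such a gene may have its highest level there. There were 224 genes higher on day 1 than on day 0 and also than on day 4, 956 and 1554 genes passing the separate tests. Independent lists of those sizes would share 85.4, a value that leaves out the shared day 1 libraries. Simulated data without effects gave 0 such genes in each of 20 draws, but called a mean of only 0.15 and 0 genes in the separate tests. That value leaves out the effects, so neither shows how many genes such lists would share. T, CDX1 and MSGN1 belong to this group: T stood at 0.504 ± 0.128, 456 ± 89.4 and 1.59 ± 0.855 CPM on days 0, 1 and 4, CDX1 at 0.157 ± 0.12, 91.5 ± 27 and 0.103 ± 0.0335, and MSGN1 at 0.019 ± 0.033, 24.4 ± 1.05 and 0.0382 ± 0.00249. The count was 130 without day 1 replicate 1 and 132 without day 1 replicate 2. Of the genes higher on day 1 than on day 0, 161 were lower on day 2 than on day 1. Both tests share the day 1 libraries, whose spread alone can put a gene in both lists, and no expected count was computed.

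**Figure D3:**
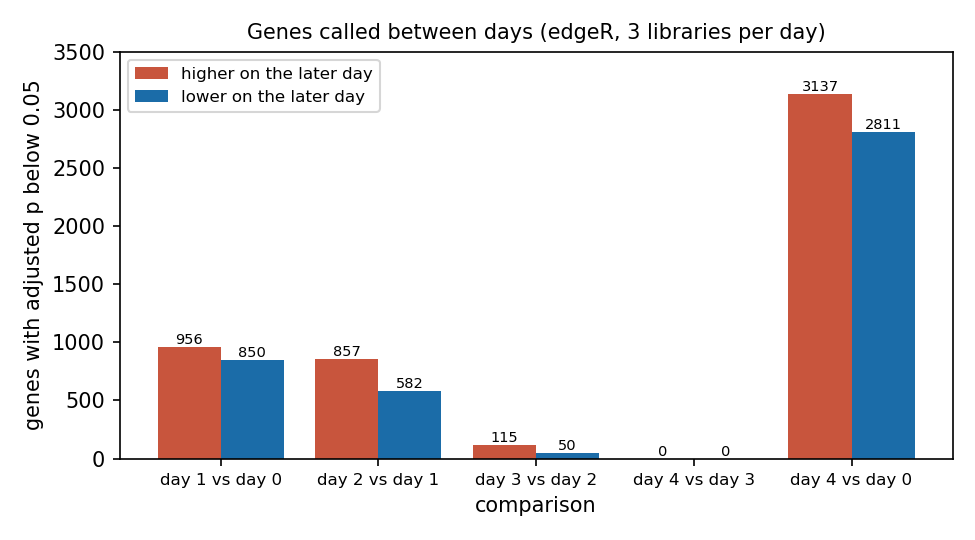
Number of genes higher and lower (bars from 0) at an adjusted p under 0.05 by edgeR's quasi-likelihood test in each of the 5 comparisons of days. Day 1 vs day 0 has 956 higher and 850 lower genes, and day 4 vs day 3 has 0 of each.

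From day 2 to day 3, some genes of DNA replication fell and a few endoderm genes rose further. CDC6, which loads the replicative helicase, went from 127 ± 25.4 to 34.7 ± 9.55 CPM (log2 fold change -1.88, SE 0.30, adjusted p = 0.0122) and the histone gene HIST1H2BK from 133 ± 52.6 to 20.4 ± 4.13 CPM. FOXA2 rose from 19.7 ± 9.43 to 139 ± 104 CPM (log2 fold change 2.82, SE 0.56, adjusted p = 0.0276), and FNDC4 had the smallest adjusted p of the named genes that rose (4.59 ± 1.53 to 88 ± 42.3 CPM, adjusted p = 0.00206). SOX17 (82.9 ± 14 and 149.5 ± 65.2 CPM) and CER1 (4537 ± 985 and 2274 ± 2030 CPM) did not pass. By edgeR, 115 genes were higher and 50 lower; with the replicate number as a block, which pairs these libraries, 371 were higher and 219 lower. These counts rested on few libraries: 4 and 1 genes without day 2 replicate 1, 5 and 2 without day 2 replicate 2, 16 and 2 without day 3 replicate 1, lower counts of 79 and 30 without replicate 4 of day 2 and of day 3, and 0 and 0 when only the 6 libraries of both days were fitted. CDC6 and HIST1H2BK were not called without day 2 replicates 1 or 2 or day 3 replicate 1 (CDC6, adjusted p = 0.0829 without day 2 replicate 1, 0.0584 without day 2 replicate 2 and 0.0722 without day 3 replicate 1; HIST1H2BK, adjusted p = 0.0734 without day 2 replicate 1, 0.0584 without day 2 replicate 2 and 0.0589 without day 3 replicate 1), and likewise FOXA2 (adjusted p = 0.124 without day 2 replicate 1, 0.12 without day 2 replicate 2 and 0.127 without day 3 replicate 1). The log2 fold change of FOXA2 was 2.06 without day 3 replicate 1, a library with 252 CPM against 116 and 48.2 in the other day 3 libraries.

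Of 30 measured S phase genes, 0 were higher, 9 lower and 21 not called (0 higher and 25 lower adjusted over the list alone). S phase genes had a median log2 fold change of -1.35 (camera adjusted p = 3.33e-26). It was called without each library in turn, and also with an estimated correlation (adjusted p = 0.0483). In the mitosis list, 0 of 30 measured genes were higher, 1 lower and 29 not called (0 higher and 11 lower adjusted over the list alone). The median of mitosis genes was -0.67 on the log2 scale (camera adjusted p = 2.28e-12; adjusted p = 0.0623 with an estimated correlation). Of 23 measured epithelial genes, 1 was higher, 0 lower and 22 not called (7 higher and 1 lower adjusted over the list alone). Epithelial genes had a median log2 fold change of 0.85 (camera adjusted p = 2.68e-05; adjusted p = 0.322 with an estimated correlation). In the FGF and ERK feedback list, 0 of 17 measured genes were higher, 0 lower and 17 not called (6 higher and 0 lower adjusted over the list alone). The median of FGF and ERK feedback genes was 0.72 on the log2 scale (camera adjusted p = 0.00278; adjusted p = 0.251 with an estimated correlation). DUSP4 was at 354 ± 26 and 768 ± 275 CPM and SPRY4 at 222 ± 107 and 278 ± 139 CPM. Of 22 measured ATF4 stress response genes, 1 was higher, 0 lower and 21 not called (4 higher and 0 lower adjusted over the list alone). ATF4 stress response genes had a median log2 fold change of 0.82 (camera adjusted p = 3.45e-05; adjusted p = 0.389 with an estimated correlation). In the heat shock list, 0 of 16 measured genes were higher, 0 lower and 16 not called (0 higher and 5 lower adjusted over the list alone). The median of heat shock genes was -0.61 on the log2 scale (camera adjusted p = 0.00129; adjusted p = 0.251 with an estimated correlation). HSP90AA1 was at 4878 ± 1720 and 2007 ± 869 CPM (adjusted p = 0.0778, and 0.0294 with the block), and it passed with adjusted p = 0.0435 without day 2 replicate 4 and 0.028 without day 3 replicate 2. Of 24 measured definitive endoderm genes, 2 were higher, 0 lower and 22 not called (5 higher and 1 lower adjusted over the list alone). Definitive endoderm genes had a median log2 fold change of 0.66 (camera adjusted p = 0.0722; adjusted p = 0.595 with an estimated correlation). The endoderm list passed with adjusted p = 0.0263 without day 2 replicate 1, 0.0403 without day 2 replicate 2, 0.00168 without day 3 replicate 1 and 0.00986 without day 3 replicate 4. The basement membrane (median 0.85, camera adjusted p = 0.00117) and BMP target (median 0.93, camera adjusted p = 0.00383) lists were called upward. So were the hypoxia target (median 0.39, camera adjusted p = 0.0304) and later endoderm and gut tube (median 1.31, camera adjusted p = 0.0401) lists. With an estimated correlation their adjusted p was 0.406, 0.487, 0.406 and 0.251. With the block, the Wnt target list passed (adjusted p = 0.0376) where it had not (adjusted p = 0.0665; adjusted p = 0.406 with an estimated correlation and without the block). The neural and surface ectoderm list did not pass with it (adjusted p = 0.0868 against 0.0492 without; adjusted p = 0.251 with an estimated correlation), and it was also lost with adjusted p = 0.0745 without day 2 replicate 1, 0.064 without day 2 replicate 4, 0.0641 without day 3 replicate 1 and 0.114 without day 3 replicate 4.

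No gene differed between day 3 and day 4 at the threshold. SOX17 was at 149.5 ± 65.2 and 175 ± 89.6 CPM, FOXA2 at 139 ± 104 and 157 ± 61.4, and CXCR4, the chemokine receptor used to mark definitive endoderm, at 79.5 ± 69.1 and 272 ± 212 CPM (log2 fold change 1.77, SE 0.61, adjusted p = 0.658). The liver and gut apolipoprotein gene APOA1 was at 7.26 ± 6.74 and 75.4 ± 21 CPM (log2 fold change 3.38, SE 0.90, adjusted p = 0.574). edgeR called 0 genes higher and 0 lower, with 1074 genes at an unadjusted p under 0.05 and a smallest adjusted p of 0.49; DESeq2 called 29 higher and 41 lower, and edgeR called 1 higher gene without day 4 replicate 2. Of 22 measured ATF4 stress response genes, 0 were higher, 0 lower and 22 not called (0 higher and 6 lower adjusted over the list alone). ATF4 stress response genes had a median log2 fold change of -1.10 (camera adjusted p = 5.6e-14; adjusted p = 0.363 with an estimated correlation). PHGDH was at 658 ± 510 and 309.6 ± 140 CPM. In the definitive endoderm list, 0 of 24 measured genes were higher, 0 lower and 24 not called, with equal counts adjusted over the list alone. The median of definitive endoderm genes was 0.32 on the log2 scale (camera adjusted p = 0.0102; adjusted p = 0.652 with an estimated correlation). That call was lost with adjusted p = 0.264 without day 3 replicate 1, 0.151 without day 3 replicate 4 and 0.668 without day 4 replicate 2. Of 30 measured S phase genes, 0 were higher, 0 lower and 30 not called, with equal counts adjusted over the list alone. S phase genes had a median log2 fold change of 0.31 (camera adjusted p = 0.00324; adjusted p = 0.652 with an estimated correlation). This was lost with adjusted p = 0.149 without day 3 replicate 4 and 0.353 without day 4 replicate 1. The epithelial (camera adjusted p = 0.0171), extraembryonic endoderm (0.0286) and basement membrane (0.0286) lists were called upward with 0 members called. With an estimated correlation their adjusted p was 0.652, 0.364 and 0.652. With the block, which pairs these libraries, the oxidative phosphorylation list (adjusted p = 0.0317 against 0.0527) and the p53 target list (adjusted p = 0.0189 against 0.0737) passed. Without the block and with an estimated correlation, the adjusted p of these lists was 0.807 and 0.363.

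Replicate 1 of days 3 and 4 stood apart from the other libraries of its days. Of 24 measured definitive endoderm genes, 13 lay below both other libraries and 4 above both on day 3, and 16 and 2 on day 4. If the libraries were exchangeable, 1 in 3 would lie below both and 1 in 3 above both. The share over all tested genes was not counted, and genes of a list may vary together, so 1 in 3 is only a rough guide. Of 19 mesoderm genes, 2 lay below and 11 above both on day 3, and 5 and 9 on day 4. The mesoderm gene HAND1 was at 262 CPM against 47.1 and 107 on day 3 and at 109 against 27.2 and 98.1 on day 4. These counts and genes were chosen after the values were seen. CER1 was at 478 CPM in day 3 replicate 1 against 4478 and 1866 in replicates 2 and 4, and at 397 against 2683 and 1958 on day 4. LEFTY1, a Nodal inhibitor, was at 0.72 against 253 and 29.8 CPM on day 3 and at 1.2 against 1522 and 425 on day 4, and GSC, an organiser gene, at 1.64 against 39.1 and 91.4 and at 1.9 against 201 and 105 CPM. FOXA2 was higher in replicate 1 on day 3, at 252 against 116 and 48.2 CPM, and lay between the others on day 4, at 171 against 210.0 and 89.6 CPM. Without both libraries, an alternative added after the data were seen, 57 genes were higher and 11 lower on day 3 than on day 2, and 3250 were higher and 2890 lower on day 4 than on day 0.

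The ends of the course differed most. On day 4, endoderm genes stood far above their day 0 levels: SOX17 went from 0.844 ± 0.157 to 175 ± 89.6 CPM (log2 fold change 7.69, SE 0.61, adjusted p = 5.59e-07), GATA4 from 1.72 ± 0.642 to 379.9 ± 155 CPM, CXCR4 from 1.46 ± 0.365 to 272 ± 212 CPM and FOXA2 from 10.5 ± 3.86 to 157 ± 61.4 CPM. Pluripotency genes were lower: SOX2 went to 8.17 ± 5.74 CPM (log2 fold change -4.62, SE 0.61), NANOG from 174 ± 55.7 to 28.9 ± 24.1 CPM (log2 fold change -2.59, SE 0.61) and POU5F1 from 449 ± 276 to 54.6 ± 56 CPM (log2 fold change -3.04, SE 0.93, adjusted p = 0.020). The POU5F1 call was lost with adjusted p = 0.0715 without day 0 replicate 4, 0.0643 without day 4 replicate 1 and 0.0924 without day 4 replicate 2. By edgeR, 3137 genes were higher and 2811 lower, with 1613 lower without day 4 replicate 2.

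Of 24 measured definitive endoderm genes, 23 were higher, 0 lower and 1 not called, with equal counts adjusted over the list alone. Definitive endoderm genes had a median log2 fold change of 6.39 (camera adjusted p = 2.34e-25). CER1 rose from 14.2 ± 1.93 to 1679 ± 1170 CPM and ERBB4 from 3.8 ± 2.55 to 1113 ± 651 CPM. In the later endoderm and gut tube list, 7 of 15 measured genes were higher, 4 lower and 4 not called, with equal counts adjusted over the list alone. The median of later endoderm and gut tube genes was 2.16 on the log2 scale (camera adjusted p = 0.114). HNF4A (7.84, SE 1.14) and APOA1 (6.18, SE 1.03) rose. Of 14 measured extraembryonic endoderm genes, 10 were higher, 1 lower and 3 not called, with equal counts adjusted over the list alone. Extraembryonic endoderm genes had a median log2 fold change of 2.59 (camera adjusted p = 4.08e-05). In the pluripotency list, 3 of 22 measured genes were higher, 13 lower and 6 not called (3 higher and 15 lower adjusted over the list alone). The median of pluripotency genes was -2.49 on the log2 scale (camera adjusted p = 1.1e-07). FOXD3 fell (-5.27, SE 0.59), as did TERF1 (-4.28, SE 0.50), a telomere protein gene. Of 19 measured primitive streak genes, 15 were higher, 1 lower and 3 not called, with equal counts adjusted over the list alone. Primitive streak genes had a median log2 fold change of 5.34 (camera adjusted p = 9.33e-08; adjusted p = 0.0518 with an estimated correlation). In the activin and Nodal target list, 13 of 17 measured genes were higher, 0 lower and 4 not called (13 higher and 1 lower adjusted over the list alone). The median of activin and Nodal target genes was 4.81 on the log2 scale (camera adjusted p = 1.59e-07). EOMES rose from 2.12 ± 0.306 to 277 ± 169 CPM. Of 21 measured Wnt target genes, 15 were higher, 1 lower and 5 not called, with equal counts adjusted over the list alone. Wnt target genes had a median log2 fold change of 2.75 (camera adjusted p = 8.28e-08). LGR5 (7.44, SE 0.47), NOTUM (6.82, SE 0.58) and SP5 (6.17, SE 0.70) remained above day 0. In the BMP target list, 14 of 18 measured genes were higher, 0 lower and 4 not called (15 higher and 0 lower adjusted over the list alone). The median of BMP target genes was 4.60 on the log2 scale (camera adjusted p = 7.74e-11; adjusted p = 0.107 with an estimated correlation). SMAD6 rose (6.77, SE 0.58). Of 19 measured mesoderm genes, 10 were higher, 0 lower and 9 not called, with equal counts adjusted over the list alone. Mesoderm genes had a median log2 fold change of 3.23 (camera adjusted p = 8.12e-04; adjusted p = 0.241 with an estimated correlation). HAND1 (6.30, SE 0.77) and FOXF1 (5.77, SE 0.70) rose. Named for the size of their change were CSF3R (9.04, SE 1.00) and GYPE (8.43, SE 0.84), which rose, and SPIB (-7.26, SE 0.76) and IDO1 (-7.05, SE 0.47), which fell.

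In the mesenchymal transition list, 15 of 21 measured genes were higher, 1 lower and 5 not called (16 higher and 1 lower adjusted over the list alone). The median of mesenchymal transition genes was 3.11 on the log2 scale (camera adjusted p = 6.27e-12). The intermediate filament gene VIM rose from 87.1 ± 32.2 to 1514 ± 563 CPM and the fibronectin receptor gene ITGA5 from 22.5 ± 9.01 to 585 ± 100 CPM. Of 23 measured epithelial genes, 2 were higher, 10 lower and 11 not called, with equal counts adjusted over the list alone. Epithelial genes had a median log2 fold change of -1.31 (camera adjusted p = 0.012; adjusted p = 0.461 with an estimated correlation). CDH1 fell from 302 ± 76.6 to 26.3 ± 24.3 CPM and GRHL2 from 36.5 ± 7.05 to 1.66 ± 0.793 CPM. In the basement membrane list, 10 of 20 measured genes were higher, 0 lower and 10 not called (11 higher and 0 lower adjusted over the list alone). The median of basement membrane genes was 1.31 on the log2 scale (camera adjusted p = 2.98e-04; adjusted p = 0.241 with an estimated correlation). COL4A2 (3.27, SE 0.39) and HSPG2 (2.78, SE 0.52) rose. Of 30 measured S phase genes, 0 were higher, 21 lower and 9 not called (0 higher and 23 lower adjusted over the list alone). S phase genes had a median log2 fold change of -1.47 (camera adjusted p = 3.58e-08; adjusted p = 0.116 with an estimated correlation). MCM4 fell from 688 ± 153 to 156 ± 86.9 CPM. The mitosis list was also called lower, with 7 of 30 members lower (median -0.51, camera adjusted p = 0.0124). So was the oxidative phosphorylation list, with 14 of 56 members lower (median -0.41, camera adjusted p = 0.0351). With an estimated correlation their adjusted p was 0.347 and 0.721. In the cholesterol synthesis list, 0 of 25 measured genes were higher, 12 lower and 13 not called (0 higher and 13 lower adjusted over the list alone). The median of cholesterol synthesis genes was -1.14 on the log2 scale (camera adjusted p = 1.51e-04; adjusted p = 0.149 with an estimated correlation). HMGCS1 fell from 2223 ± 785 to 421 ± 37.7 CPM. Of 17 measured hypoxia target genes, 8 were higher, 1 lower and 8 not called, with equal counts adjusted over the list alone. Hypoxia target genes had a median log2 fold change of 0.94 (camera adjusted p = 0.0103; adjusted p = 0.288 with an estimated correlation). BNIP3 rose from 31.4 ± 14.2 to 408 ± 375 CPM. In the glycolysis list, 6 of 21 measured genes were higher, 3 lower and 12 not called, with equal counts adjusted over the list alone. The median of glycolysis genes was 0.35 on the log2 scale (camera adjusted p = 0.637). SLC2A3 rose from 933 ± 135 to 8433 ± 2350 CPM and PKM2 from 1157 ± 709 to 7560 ± 4360 CPM. PKM2 is here an older symbol of the gene PKM, and counts per gene do not separate its splice forms. Of 16 measured heat shock genes, 1 was higher, 8 lower and 7 not called (2 higher and 10 lower adjusted over the list alone). Heat shock genes had a median log2 fold change of -1.16 (camera adjusted p = 0.00964; adjusted p = 0.241 with an estimated correlation). The heat shock call was lost with adjusted p = 0.082 without day 4 replicate 1; HSPA8 fell from 4943 ± 952 to 1408 ± 408 CPM. In the zinc and copper handling list, 5 of 30 measured genes were higher, 6 lower and 19 not called, with equal counts adjusted over the list alone. The median of zinc and copper handling genes was 0.30 on the log2 scale (camera adjusted p = 0.877). The zinc transporter genes SLC30A4 (6.37, SE 0.79) and SLC39A4 (2.43, SE 0.56) rose. By fry's test for a shared direction, no list passed on day 4 vs day 3 (smallest adjusted p = 0.284). Its test for mixed directions called the later endoderm and gut tube list and the blood and endothelium list there (each adjusted p = 0.021). The metallothionein list passed by fry in no comparison (adjusted p = 0.118 on day 1 and 0.0874 on day 4, each against day 0). The BMP target and mesoderm lists passed by fry on day 1 vs day 0 (adjusted p = 6.9e-04 and 9.0e-04). Other fry results are not reported here. With an estimated correlation, the list calls that held were those of the pluripotency, primitive streak, Wnt target, activin and Nodal target and mesenchymal transition lists on day 1 vs day 0, the definitive endoderm and Wnt target lists on day 2 vs day 1, the S phase list on day 3 vs day 2, and the pluripotency, definitive endoderm, extraembryonic endoderm, Wnt target, activin and Nodal target and mesenchymal transition lists on day 4 vs day 0.

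Metallothioneins, small cysteine-rich proteins that bind zinc and copper and the family named in the series title, had their highest mean on day 0. The family sum was 177, 21.2 and 46.2 CPM in the day 0 libraries and 15.6, 8.52 and 10.3 CPM on day 1, a log2 fold change of -2.83 (SE 0.81, adjusted p = 0.0347). It was 3.57, 3.69 and 8.85 CPM on day 2, 1.18, 2.85 and 9.39 on day 3 and 6.81, 9.12 and 21.9 on day 4, with a log2 fold change of -2.69 (adjusted p = 0.0171) between day 4 and day 0. Day 0 replicate 1 had the highest level. Without it the log2 fold changes of the sum were -1.56 (adjusted p = 0.297) on day 1 and -1.39 (adjusted p = 0.188) on day 4. The same library had the highest ribosomal protein share, 7.35%.

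Between day 0 and day 1, of 7 measured metallothionein genes, 0 were higher, 2 lower and 5 not called (0 higher and 6 lower adjusted over the list alone). Metallothionein genes had a median log2 fold change of -2.72 (camera adjusted p = 0.00865; adjusted p = 0.438 with an estimated correlation). The list call was lost with adjusted p = 0.103 without day 0 replicate 1. MT1X fell from 43.7 ± 41.4 to 5.43 ± 1.66 CPM (adjusted p = 0.0315) and MT1F from 4.09 ± 5.07 to 0.45 ± 0.15 CPM (adjusted p = 0.0216). Neither call held without day 0 replicate 1 or without any 1 of the day 1 libraries (MT1X, adjusted p = 0.228 without day 0 replicate 1, 0.0905 without day 1 replicate 1, 0.136 without day 1 replicate 2 and 0.117 without day 1 replicate 4; MT1F, adjusted p = 0.302 without day 0 replicate 1, 0.0894 without day 1 replicate 1, 0.068 without day 1 replicate 2 and 0.103 without day 1 replicate 4). MT2A stood at 14.7 ± 14.7 and 2.67 ± 0.543 CPM and did not pass (adjusted p = 0.0852). Between day 0 and day 4, in the metallothionein list, 0 of 7 measured genes were higher, 4 lower and 3 not called (0 higher and 5 lower adjusted over the list alone). The median of metallothionein genes was -2.88 on the log2 scale (camera adjusted p = 0.0523; adjusted p = 0.50 with an estimated correlation). This list passed with adjusted p = 0.00347 without day 0 replicate 2 and 0.026 without day 4 replicate 4, and with length and GC trends removed (median -2.36, adjusted p = 0.0295), where MT1H (adjusted p = 0.0321) and MT2A (adjusted p = 0.0228) were also called lower. MT1X was lower on day 4, at 2.5 ± 1.51 CPM (log2 fold change -4.13, SE 0.89, adjusted p = 0.00245), and that call held without each library of both days. MT1F (adjusted p = 0.0828 without day 0 replicate 1), MT1E (adjusted p = 0.329 without day 0 replicate 1, 0.0868 without day 4 replicate 2 and 0.0505 without day 4 replicate 4) and MT1G (adjusted p = 0.335 without day 0 replicate 1, 0.0879 without day 4 replicate 1, 0.102 without day 4 replicate 2 and 0.123 without day 4 replicate 4) were also called lower and lost the call in those fits. From day 3 to day 4 the list passed with 0 members called (median 1.80 on the log2 scale, camera adjusted p = 9.18e-04; adjusted p = 0.58 with an estimated correlation), with MT2A at 1.05 ± 0.952 and 6.08 ± 5.53 CPM (adjusted p = 0.658). That call was lost with adjusted p = 0.0743 without day 3 replicate 1. MT3, a brain-enriched member that the filter on low counts removed, had no count on days 0 and 1 and was at 0.0785, 1.56 and 1.52 CPM in the day 4 libraries. Members and pseudogenes of this family are nearly identical, and reads may have been shared among them, so levels of single members are uncertain.

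**Figure D4:**
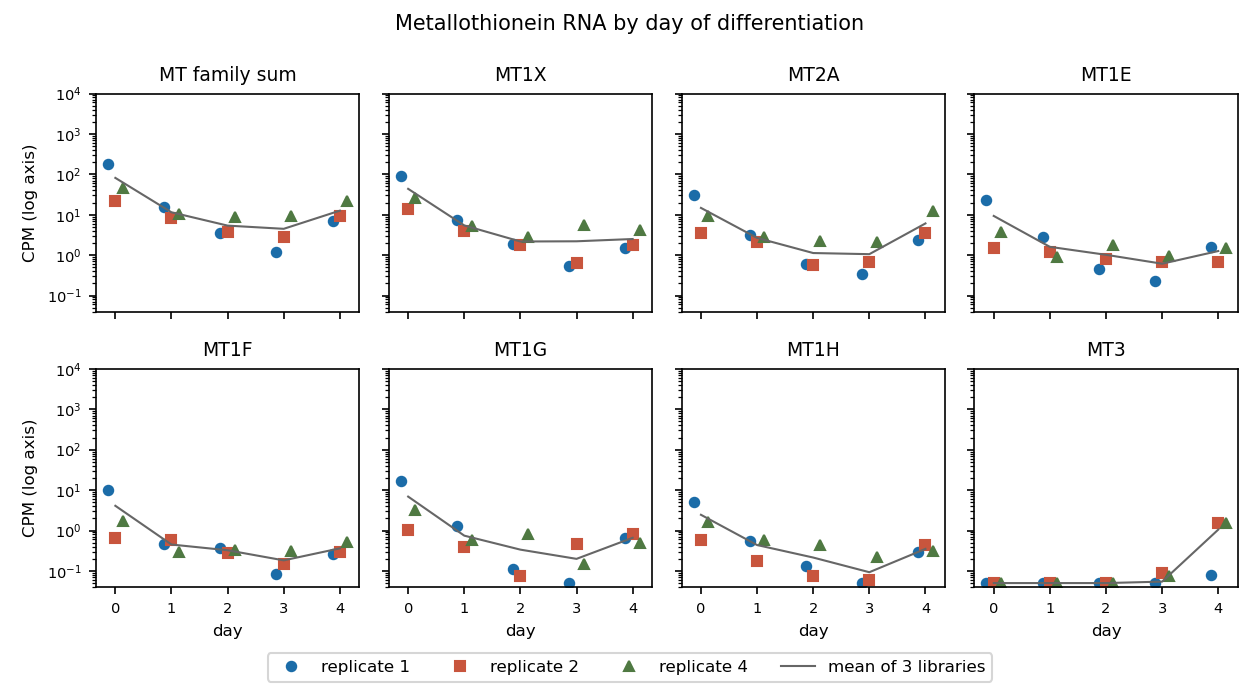
CPM (log axis, values under 0.05 drawn at 0.05) of the metallothionein family sum and of 7 members by day, each point a library. The family sum in the day 0 libraries is 177, 21.2 and 46.2 CPM, above each of the day 1 libraries.

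Libraries of the same day differed in the share of counts in ribosomal protein genes. It was 7.35%, 2.13% and 4.74% on day 0, 4.07%, 2.67% and 4.02% on day 1, 2.23%, 2.27% and 5.48% on day 2, 2.27%, 2.49% and 6.24% on day 3 and 2.22%, 4.27% and 4.89% on day 4, for replicates 1, 2 and 4. The median of 85 other genes with transcripts under 800 bases, as a log2 deviation from the mean of the day, was 0.97, -0.94 and -0.06 on day 0 and -0.60, -0.08 and 0.68 on day 3.

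**Figure D5:**
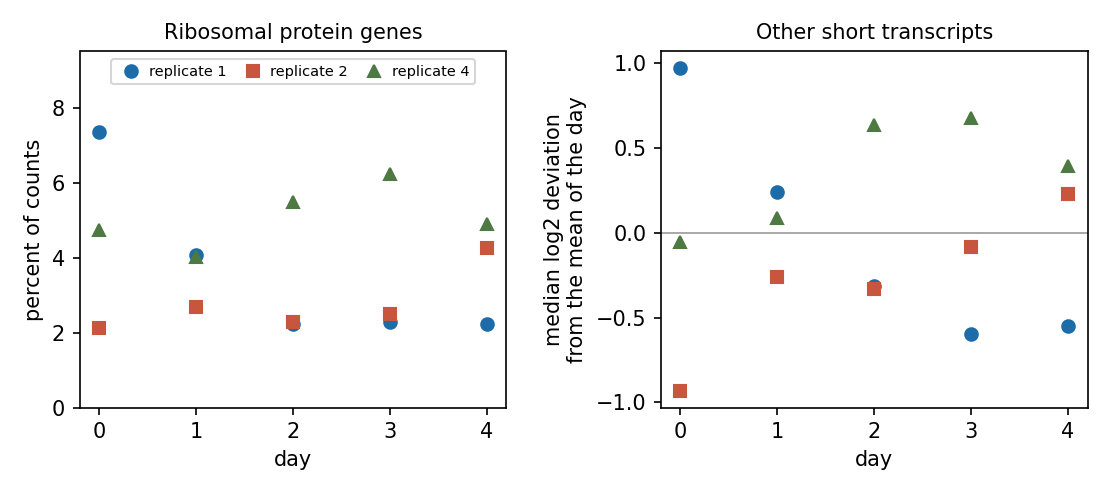
Share of counts in ribosomal protein genes (percent) and median log2 deviation of short transcripts from the mean of their day, by day, each point a library. On day 0 the shares are 7.35%, 2.13% and 4.74%, and the deviations follow in the same order of libraries with 0.97, -0.94 and -0.06.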

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

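The fits with trends removed, with counts halved and without replicate 1 of days 3 and 4 were chosen only after the results were seen. Each pair of numbers gives genes higher and then lower. DESeq2 called 1442 genes lower on day 1 vs day 0, with 4 metallothioneins lower, 1398 and 1056 on day 2 vs day 1, 614 and 334 on day 3 vs day 2, 29 and 41 on day 4 vs day 3 and 1 metallothionein higher on day 4 vs day 0. Without a filter on low counts 1 metallothionein was higher on day 4 vs day 0, and with CPM over 1 in 3 libraries 1 was lower on day 1 vs day 0. A fit of only the 2 days compared gave 5 lower metallothioneins on day 1 vs day 0, 1506 and 1308 genes with 1 lower metallothionein on day 2 vs day 1, 0 and 0 on day 3 vs day 2 and 1798 lower on day 4 vs day 0. The test against a 1.5-fold change gave 495 lower genes with 1 lower metallothionein on day 1 vs day 0, 517 and 293 on day 2 vs day 1, 40 and 6 on day 3 vs day 2 and 1859 lower on day 4 vs day 0, a stricter test by construction. With length and GC trends removed there were 1483 and 1297 on day 1 vs day 0, 1396 and 1300 on day 2 vs day 1, 501 and 410 on day 3 vs day 2, and 385 genes above both ends on day 1. Without replicate 1 of days 3 and 4, day 3 vs day 2 gave 57 and 11, and 1 metallothionein was higher on day 4 vs day 0. The cause of these changes was not tested.

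With the replicate block, counts were 1608 and 1305 on day 1 vs day 0, 1298 and 1168 on day 2 vs day 1, 371 and 219 on day 3 vs day 2 and 360 genes above both ends on day 1. With the block and the trends removed they were 1993 and 1643, 1699 and 1846, and 754 and 672 for those comparisons, 9952 genes over the course and 545 above both ends. Pairing was not found for day 1 vs day 0, day 2 vs day 1 and day 4 vs day 0, where the lowest correlations of same-numbered libraries were 0.037, -0.075 and -0.19 and 4, 4 and 3 of 6 libraries correlated best with their own number. For day 3 vs day 2 the block also called KLF5, RUNX1 and HSP90AA1. Among the named genes and the gene lists alone, and apart from the values given with the report's comparisons, it changed no other call of the paired days.

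Leaving out each library in turn gave, on day 1 vs day 0, 624 to 1484 higher, 380 to 1155 lower and 0 to 3 lower metallothioneins; on day 2 vs day 1, 384 to 775 and 183 to 447; on day 3 vs day 2, 4 to 164 and 1 to 79; on day 4 vs day 3, 0 to 1 and 0 to 0; on day 4 vs day 0, 2438 to 3707 higher, 1613 to 2933 lower, 0 to 1 higher and 1 to 5 lower metallothioneins; 5189 to 7040 genes over the course; and 130 to 236 above both ends on day 1. The oxidative phosphorylation list of day 1 vs day 0 had a median of -0.41, and of -0.75 to 0.03 with a library left out, the latter value without day 0 replicate 1. Of 300 calls of named genes, 300 were kept with DESeq2's size factors, 292 with library totals, 298 without a filter, 289 with trends removed and 252 in the 1.5-fold test, and 268 of 299 with only the 2 days fitted. Of those that involve a library left out, 2 of 24 were kept without day 3 replicate 1, 42 of 90 and 48 of 90 without day 2 replicates 2 and 1, and at most 122 of 126, without day 4 replicate 1; none reversed. Of 60 list calls, 59 were kept with counts halved, 60 with library totals and 51 with trends removed, where 5 others passed: metallothioneins on day 4 vs day 0, and mesoderm, mitosis, p53 target and primitive streak on day 4 vs day 3. With a library left out, 12 of 18 and 17 of 24 were kept without day 3 replicate 1 and without day 4 replicate 1, and 29 of 33 with 1 reversed, the oxidative phosphorylation list, without day 0 replicate 1. Depth limits genes near 3 counts; for abundant genes the spread between libraries, not depth, set the error.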

Other observations

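Tests of gene families, of metallothioneins with trends removed and without day 0 replicate 1, of the share of endoderm cells and of an earlier day were chosen only after the results were seen, as were the genes named with the families. The families, 10 groups of genes by name in 5 comparisons, made 50 tests that were adjusted together. HOX genes, which pattern the body axis, rose on day 1: of 21 measured, 16 were higher and 0 lower than on day 0 (median log2 fold change 5.71, camera adjusted p = 3.49e-20, and adjusted p = 0.00963 with an estimated correlation). HOXB1 went from 0.0199 ± 0.0344 to 1.35 ± 0.233 CPM and back to 0.00913 ± 0.0158 on day 2. HOXB3, by contrast, was at 0.0938 ± 0.0648 CPM on day 0, 4.91 ± 1.57 on day 1 and 17 ± 3.4 on day 4, and HOXB2, which rose again on day 2 (adjusted p = 3.94e-04), at 0.072 ± 0.0415, 0.768 ± 0.296 and 10.8 ± 1.5. On day 4, 11 HOX genes were above day 0 and 0 below.

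Collagen genes were higher at the end of the course: of 42 measured, 23 were higher and 3 lower on day 4 than on day 0 (median log2 fold change 1.76, camera adjusted p = 4.99e-07, and adjusted p = 0.0684 with an estimated correlation). COL5A2 rose from 39.8 ± 2.65 to 5305 ± 1420 CPM and COL6A1 from 57.8 ± 42 to 990 ± 373 CPM, and COL14A1 fell from 38.8 ± 10 to 8.33 ± 2.0 CPM. Of 50 histone cluster genes, 21 were lower and 0 higher on day 4 than on day 0 (median -2.41, camera adjusted p = 1.03e-07, and adjusted p = 0.40 with an estimated correlation). HIST1H2AC fell from 18 ± 6.51 to 1.24 ± 0.592 CPM. Most replication-dependent histone transcripts lack a polyA tail, so in polyA-selected libraries these counts cover only part of that RNA.

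Other splits of the libraries were fitted to see how often they gave as many calls. For 3 against 3 libraries there are 10 splits, too few for a share under 0.05. With only the days compared in the fit, the real split, 1 of 10 with as many calls, gave 2212 genes on day 1 vs day 0, 2814 on day 2 vs day 1 and 4082 on day 4 vs day 0, against at most 0, 0 and 0 in the others. For day 3 vs day 2 the real split gave 0 and the highest other 3, and for day 4 vs day 3 they gave 0 and 3351, so that all 10 splits gave at least as many calls. In both comparisons the splits that part every same-numbered pair, as the real one does, gave 0 genes, and those with 3 and 3351 kept some pairs together. The split of days 3 and 4 with 3351 genes points to a structure of the samples: it set replicates 1 and 2 of day 3 and replicate 1 of day 4, with short-transcript deviations of -0.60, -0.08 and -0.55, against the other 3 libraries, with 0.68, 0.23 and 0.39, and it gave 177 genes once length and GC trends were removed. For the joint test, 1 of 100 splits of the 15 libraries, the real one, gave as many as 6498 genes, with at most 1101 in the others. These splits ignore that same-numbered libraries of days 2 to 4 pair. In 100 splits added after the results were seen, days were shuffled within each number. Only 1, the real one, gave as many, with at most 1144 in the others. A chance assignment of these libraries to days is thus an unlikely source of the joint count. The smallest share that 100 splits can give is 1 in 100, and whether the libraries of a day are separate cultures is not known. For genes above both ends on day 1 it was 1 of the first 100 splits, the real one, with 224 genes against at most 8, which follows from there being differences between days and does not test whether the overlap exceeds that of lists sharing the day 1 libraries.

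The decrease of metallothionein RNA on day 1 was weighed against technical causes. The median log2 fold change of the 7 tested members was -2.53 with length and GC trends removed, where MT1F, MT1X and MT2A were called (MT2A adjusted p = 0.00801), which argues against those trends as the whole cause. Without day 0 replicate 1 the fold of the family sum was -1.56 (SE 0.74, unadjusted p = 0.0555), so whether that library alone made the difference stays open, although each remaining day 0 library lay above each day 1 library. SLC30A1, a zinc exporter gene under the same metal-sensing regulator, had a log2 fold change of -0.99 (SE 0.36, adjusted p = 0.0947), which neither shows nor excludes a change of zinc supply. Medium and day changed together, so a change of medium and one of cell state remain open and cannot be told apart here.

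Libraries of a day differed in their ribosomal protein share, and a candidate explanation is a trend with transcript length across all genes. Over the 15 libraries, within days, the share correlated with the level of 85 short transcripts of other genes (Pearson r = 0.966, permutation p = 2.2e-04, adjusted over 2 relations 4.4e-04; Spearman rho = 0.979, permutation p = 2e-04; r = 0.95 without the 2 farthest libraries), as such a trend would need. With the total count it gave r = -0.36 (permutation p = 0.301, adjusted 0.301; rho = -0.482, permutation p = 0.128; r = -0.312 without the 2 farthest libraries), which leaves a role of depth open. These permutations treat the days as independent, although same-numbered libraries of days 2 to 4 pair, so their p may be too small; shuffled together on those days, a test added after the results were seen, the 216 arrangements gave p = 0.00463 (adjusted 0.00926) and 0.519 (adjusted 0.519). No label gives RNA quality or a library batch, so the origin of the trend was not tested, nor was a biological one.

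Replicate 1 of days 3 and 4 had low CER1, LEFTY1 and GSC. Removing length and GC trends left CER1 lower than the mean of the other libraries (log2 difference -2.28 or lower on both days), which argues against those trends. Day 2 cells in these tubes are argued against by CER1 on day 2, at 3458 CPM or more in each library, and day 1 cells by FOXA2, at 252 and 171 CPM against 1.97 ± 0.499 on day 1; Spearman correlations over genes decided nothing, as the highest with day 2 (0.962 and 0.965) lay within the range with other numbers of days 3 and 4 (0.944 to 0.972 and 0.928 to 0.974). A lower share of endoderm cells could not be decided: FOXA2 was higher by 1.75 on the log2 scale in day 3 replicate 1, but on day 4 it lay between the other libraries (171 against 210.0 and 89.6 CPM). GATA4 (log2 differences -0.41 and -1.23 on days 3 and 4) and CXCR4 (-1.18 and -1.67) lay below both other libraries on both days. SOX17 (-0.33 and -1.59) lay below both on day 4 only. A culture that took another course, within endoderm or with more mesoderm gene expression, may fit these values as well. Of 19 mesoderm genes, 11 and 9 lay above both other libraries on days 3 and 4, and 2 and 5 below both. With exchangeable libraries 1 in 3 would lie above both, but the share over all tested genes was not counted. Genes of a list may also vary together, so these counts are weak support, that of day 4 in particular. The labels give no difference between the replicates that would test such a course.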
